A study of Mus musculus with 6 samples.

How the data were processed

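RNA from freshly sorted and from cultured mouse satellite cells was biotin-labelled with a whole-transcript terminal labelling kit and hybridised to Affymetrix arrays, per the labels' protocols. The value table deposited by the authors holds log2 expression values of 35556 probe sets on 6 arrays, with no missing value. Per the submitters' processing notes, RMA and the package oligo were used, with no version stated. RMA subtracts background, normalizes quantiles across arrays and summarises probes by median polish, and compresses differences near the background. The array medians over all probe sets lay between 3.10 and 3.15, the maxima between 14.7 and 15.2, and the bright values were dimmer on cultured replicates 2 and 3, so the distributions as deposited were not identical. Which probes or steps made this difference, and the genome build, are not given in the sources used here. No scanner files were used.

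Probe sets were named through the platform annotation and the gene names of assembly GRCm38.p6, with no coordinates. Of the 35556 probe sets, 21789 had 1 gene, 1621 had several and were not named, and 12146 were unlisted. For each gene the probe set with the highest mean over the 6 arrays was kept, which left 19938 genes. Of 999 genes with several probe sets, 93 had at least 1 probe set past the test, 34 of them had all past it in 1 direction, and none had opposite calls. Near-identical genes can share probes: Hspa1a has a near-identical neighbour, and ribosomal proteins have processed copies.

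The main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited log2 values, the group as the only term, no filter on dim genes and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05, and a 2-fold change is an absolute log2 fold change of at least 1. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the 20 pathway lists and, separately, the 10 other-cell-type lists with at least 5 measured genes. An estimated correlation and fry were alternatives. With the preset correlation 15 pathway lists passed, 11 lower and 4 higher, and with an estimated correlation 3 did: the AP-1 family, other immediate early genes and inflammatory cytokines. For brightness-matched lists, 10000 random lists were drawn from the 50 genes nearest to each member in mean over the 6 arrays. A change in culture moves that mean, so a list with a large fall can be matched to genes dimmer on the fresh arrays.

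Background was taken as the 95th percentile of 1194 olfactory and vomeronasal receptor genes, 3.21 on fresh and 3.30 on cultured arrays. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Fos and the AP-1 family, the 10 highest and 10 lowest fold changes past the test whose groups do not overlap (leaving out predicted, small RNA and receptor genes), and the 4 members of each list with the largest absolute fold change, plus members that describe a split. Pax7, Myod1, Myog and Thbs4 were added after their values were seen. Other settings were a replicate block, a trended and robust prior, array weights, rescaling, filters on dim genes, other probe set rules, unequal variances, treat against 1.2-fold, set tests and leaving out each array.

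The code was tested on simulated data. For cultured against fresh over 19938 genes, 200 genes were changed. At a log2 change of 1, 34 of 50 were recovered, and at 2, 3 and 4 all 50 were, with 13 false calls. With the mitosis list moved by 1, camera called it and no other list, and 20 draws with nothing moved gave 4 calls over all 30 lists. The simulated arrays hold no correlation between genes, and each gene has the same spread in both groups. In the data the spreads can differ, for example for Pclaf with an SD of 0.20 in fresh and 1.37 in cultured cells. The recovery and the false calls therefore need not carry over to the data.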

Results

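Gene expression was measured on 6 whole-transcript mouse arrays, 3 from freshly sorted muscle satellite cells and 3 from satellite cells grown in culture for 5 days. Satellite cells are the resident stem cells of skeletal muscle. They were sorted from limb and trunk muscles of 2-month-old C57BL/6J mice as cells carrying beta-1 integrin and CXCR4 and lacking CD45, CD31, CD11b, Ter119 and Sca1. The cultured cells were kept on collagen and laminin in growth medium with 20% horse serum and daily basic fibroblast growth factor at 5 ng/ml. After 1 probe set was kept per gene, 19938 genes were compared, and every group mean below is of 3 arrays (n = 3) on the log2 scale. The number of arrays limits the precision of every value. The labels speak of 3 mice without tying an array to a mouse, so the p-values measure the spread between these samples, which may be partly technical.

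The comparison asked which transcripts differ between satellite cells freshly sorted from muscle and the same kind of cells after 5 days in growth medium. The lowest fold changes in the cultured cells were those of Hspa1a, an inducible heat shock protein, with a log2 fold change of -7.29 ± 0.24 (SE), and of the metallothionein Mt2 at -7.10 ± 0.33, whose fresh level of 14.72 was near the top of the array range. Fos, the gene in the title of the series and a subunit of the transcription factor AP-1, fell by 6.03 ± 0.18 on the log2 scale, a 65.2-fold difference. The strongest rises were in S100a4, a calcium-binding protein of motile cells, at 4.19 ± 0.67, in the replication clamp partner Pclaf at 3.95 ± 0.59, from a fresh level within background, and in the slow-muscle troponin Tnnc1 at 3.53 ± 0.49. With limma and Benjamini-Hochberg adjustment, 861 genes passed an adjusted p of 0.05, 671 lower and 190 higher in the cultured cells.

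Of the 861 genes, 689 changed at least 2-fold, 580 of them downward and 109 upward. The 3 cultured values lay wholly outside the 3 fresh values for all 861 genes, and for 4630 of the 19938 genes tested, 23.2% against the 10% that chance gives. The median log2 fold change of all genes was 0.04. The count depended on single arrays. It was 478 without fresh replicate 2, 471 without fresh replicate 3, 448 without cultured replicate 3 and 1517 without cultured replicate 1. The share of changed genes that were higher in culture, 22.1%, rose to 38.8% after a further quantile normalization and to 99.4% when the arrays were centred on ribosomal proteins, a setting that adds 1.81 to every log2 fold change, so that falls smaller than this turn positive by construction and changes relative to all genes stay as they are. Directions below are those of the deposited scale. On it, genes with a mean above 11 had a median difference from the fresh mean of -3.33 and -2.87 on cultured replicates 2 and 3. On cultured replicate 1 it was -0.09, so the balance of falls and rises need not be that of the cells.

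Among the remaining 10 genes with the lowest fold changes were the chaperones Dnajb1 (-6.57) and Hspb1 (-6.30), the neutrophil-attracting chemokine Cxcl1 (-5.93), the quiescent satellite cell marker Chodl (-5.90), the secreted glutathione peroxidase Gpx3 (-5.65), the complement inhibitor Serping1 (-5.33) and the metallothionein Mt1 (-5.29). Mt2 and Mt1 averaged 14.72 and 14.44 on the fresh arrays, where the highest probe set reached 14.93, so their falls can be larger than given; whether such probe sets were saturated is not given in the sources used here. Chodl averaged 8.39 in fresh and 2.49 in cultured cells, the latter within background, taken as the 95th percentile of olfactory and vomeronasal receptor genes, which was 3.30 on the cultured and 3.21 on the fresh arrays. Among the 10 highest fold changes were the replication-dependent histone H2ac4 (3.34), the mast cell receptor Milr1 (3.20), the basophil protease Mcpt8 (3.09), the cardiac actin Actc1 (2.87), the p53 target Ccng1 (2.80), the ribonucleotide reductase subunit Rrm2 (2.79) and the cardiac troponin Tnnt2 (2.72). Where a group mean lay within background, the fold change is better read as a bound against that level. On the log2 scale these bounds, for the probe sets used and over the 6 arrays, were 3.55, 2.88 and 2.09 upward for Pclaf, Milr1 and Mcpt8. A further probe set of Pclaf gave 3.19. Downward, the bounds were -5.09 for Chodl, -5.04 for Serping1, -4.33 for Rgs2, -4.14 for Dpt and -4.09 for Dcn. The bounds come from group means and make no allowance for the spread between arrays. For Irf1, Cxcl2, Fas, Pfkp and Bhlhe40 the bounds were -3.20, -3.16, -2.39, -1.86 and -1.76, and for Ccna2 the bound was 1.70. A further probe set of Irf1, above background in both groups, gave -1.37, so that the size of its fall is uncertain. Without cultured replicate 1, S100a4 was at 3.33, Pclaf at 3.19 and B2m at -3.92. Without cultured replicate 3, Tnnc1 was at 2.88, Actc1 at 2.03, Mylpf at 1.63 and Myog at 1.65, and without fresh replicate 3 Dcn was at -5.28. S100a4 and Pclaf lost their call without fresh replicate 2 or fresh replicate 3, at adjusted p of up to 0.0693 and 0.0524. Actc1 lost it without any 1 of the fresh arrays, and Ccng1 without any 1 of the fresh arrays or cultured replicate 3.

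**Figure D1:**
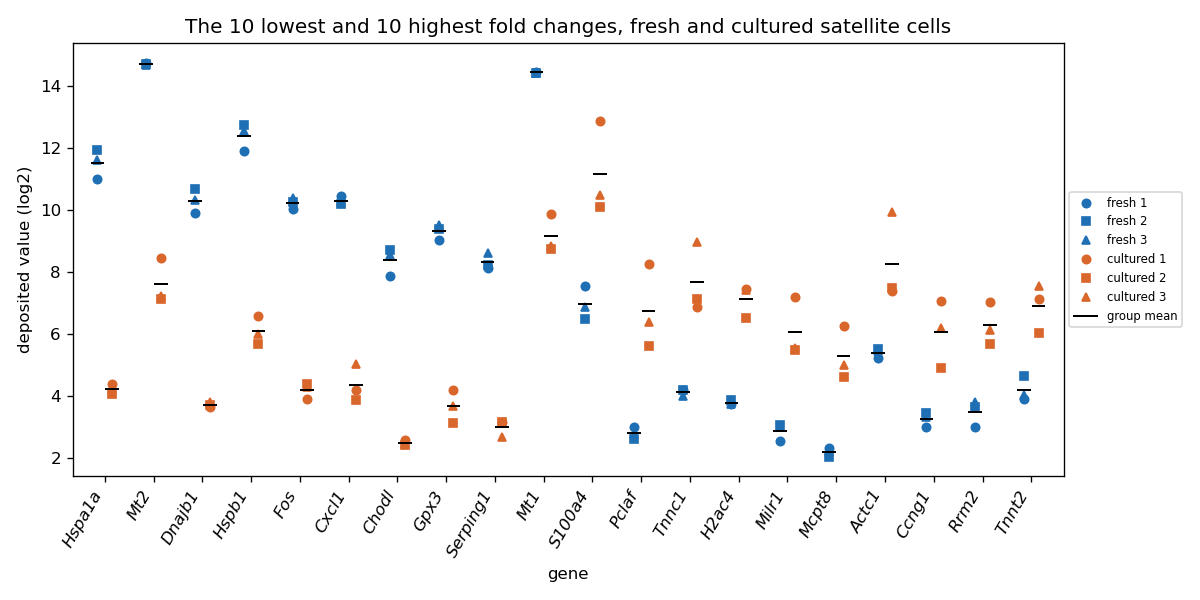
Deposited log2 value (vertical axis) on each of the 6 arrays for the 10 genes with the lowest and the 10 with the highest fold change, with fresh arrays in blue, cultured arrays in orange, a marker shape per replicate number and a black bar at each group mean. By the rule that chose these genes, the 3 cultured values of each lie on one side of its 3 fresh values. Fos lies between 10.03 and 10.40 in fresh and between 3.91 and 4.40 in cultured cells.

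In the AP-1 family, of the 16 measured members, 9 fell and none rose over all genes tested, and 10 fell and 1 rose adjusted over the list alone. Fos averaged 10.23 ± 0.19 (SD) on the fresh arrays and was at 3.91, 4.40 and 4.30 on the cultured arrays, with an adjusted p of 1.01e-05. The next largest falls were in the stress-induced Atf3 (-4.35), in Fosb (-4.26), in the small Maf protein Maff (-3.97), in Jun (-3.89) and in Junb (-3.89), followed by Jund (-2.72), Mafk (-1.96) and Fosl2 (-1.20). Fosl2 lost its call without fresh replicate 2, fresh replicate 3 or cultured replicate 3, at adjusted p of up to 0.0691. Fosl1 did not pass, at -0.80 with an adjusted p of 0.0874, nor did Batf2 at 0.81 with 0.126. The values of Batf, Batf3, Jdp2, Maf and Mafg lay between -0.30 and 0.19. The list lay below all other genes in the competitive set test camera, with an adjusted p of 9.53e-14 at a preset correlation and an adjusted p of 0.0348 with an estimated correlation. The median of the list was -1.58.

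**Figure D2:**
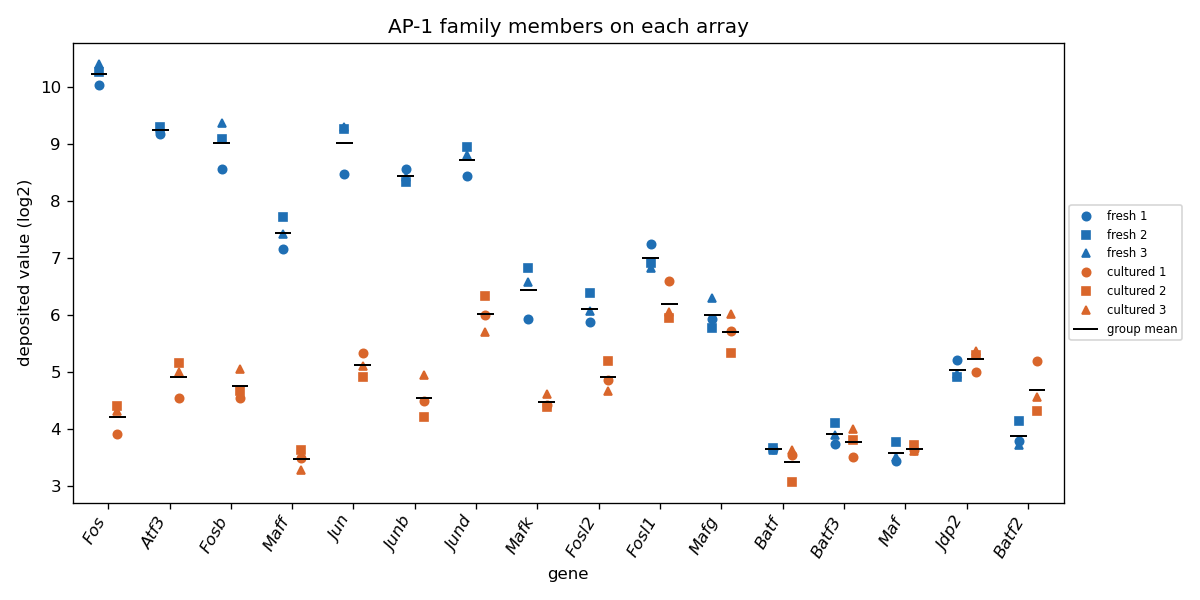
Deposited log2 value (vertical axis) of the 16 measured AP-1 family members on each array, ordered by fold change, with fresh arrays in blue, cultured arrays in orange and a black bar at each group mean. The fall is largest for Fos (-6.03) and Atf3 (-4.35), while Jdp2 (0.19) and Maf (0.08) did not pass the test.

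Other immediate early genes are switched on within minutes of a stimulus. Of 36 measured members, 26 fell and none rose, and 28 fell adjusted over the list alone. Zfp36, which destabilises cytokine mRNAs, fell by 5.27 on the log2 scale, the transcription factor Egr1 by 5.22, the antiproliferative Btg2 by 5.15 and the nuclear receptor Nr4a1 by 4.78. The list had a camera adjusted p of 4.28e-38, and an adjusted p of 0.0348 with an estimated correlation. Heat shock proteins and chaperones followed, with 11 of 16 lower and none higher, and 13 lower adjusted over the list alone. Their median was -3.53, and -2.78 after quantile normalization and -2.71 with cyclic loess. Dnajb4 fell by 4.62. The camera adjusted p was 7.04e-18 for this list, but the call was lost at an adjusted p of 0.102 with an estimated correlation. Inflammatory cytokines and NF-kB targets had 10 of 23 members lower and none higher, and 12 lower and 1 higher adjusted over the list alone. After Cxcl1 came the monocyte-attracting chemokines Ccl7 (-4.10) and Ccl2 (-3.57) and the chemokine Cxcl2 (-3.49). This list had a camera adjusted p of 1.22e-11, and an adjusted p of 0.0316 with an estimated correlation.

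Genes of satellite cell quiescence and identity fell in part. Of 36 measured members 17 fell and none rose, and 19 fell adjusted over the list alone. After Chodl and Gpx3, the regulator of G-protein signalling Rgs2 fell by 4.69 on the log2 scale, to within background, and the bone morphogenetic protein antagonist Chrdl2 by 4.26. The lineage transcription factor Pax7, named here after its value was seen, fell by 1.33 on the log2 scale with an adjusted p of 0.00378. The list had a camera adjusted p of 4.13e-15, lost at an adjusted p of 0.10 with an estimated correlation. In the Notch pathway list 3 of 21 members fell and none rose, with 5 lower and 1 higher adjusted over the list alone. The 3 were the effectors Heyl (-2.53), Hes1 (-1.52) and Hey1 (-1.36), while Rbpj, the DNA-binding partner of Notch, was at -0.88 with an adjusted p of 0.0742 and at -0.08 by a further probe set within background. Hey1 lost its call without fresh replicate 1, fresh replicate 2, cultured replicate 2 or cultured replicate 3, at adjusted p of up to 0.183, and Hes1 lost it without cultured replicate 3 at 0.0775. The Notch list had a camera adjusted p of 0.0202, lost at an adjusted p of 0.312 with an estimated correlation, and its median of -0.12 lay within the -0.16 to 0.23 that held 95% of random lists matched on brightness, a comparison added after the data were seen.

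Some muscle differentiation genes rose. Of 42 measured members of the myogenic list, 10 rose and 2 fell, and 16 rose and 2 fell adjusted over the list alone. Besides Tnnc1, Actc1 and Tnnt2, the acetylcholine receptor subunit Chrna1 rose by 2.71 on the log2 scale. The 2 that fell were the intermediate filament gene Des (-1.21) and muscle creatine kinase Ckm (-0.80). Of the myogenic regulators, named here after their values were seen, Myog was at 4.56 ± 0.25 (SD) in fresh and 6.84 ± 1.14 in cultured cells with an adjusted p of 0.0465, and Myod1 at 9.18 ± 0.49 and 8.77 ± 0.42 with an adjusted p of 0.532. Myog differed between the cultured arrays, at 5.89, 6.54 and 8.10. Myog lost its call without any 1 of the fresh arrays or cultured replicate 2, at adjusted p of up to 0.166. Mylpf, a fast myosin light chain at 2.27, lost it without any 1 of the fresh arrays, at up to 0.145. Des lost it without any 1 of the fresh arrays or cultured replicate 3, at up to 0.149, and Ckm without fresh replicate 2, fresh replicate 3, cultured replicate 2 or cultured replicate 3, at up to 0.136. Cultured replicate 3 stood apart, with a list median of 5.66 against 4.57 and 4.60 on cultured replicates 1 and 2 and 4.02, 4.01 and 4.02 on the fresh arrays, with Tnnc1 at 8.98 against 6.89 and 7.14, and with Actc1 at 9.95 against 7.38 and 7.50. The median fold change of the list was 0.65, and 0.33 without cultured replicate 3. The myogenic list had a camera adjusted p of 1.15e-05, lost at an adjusted p of 0.508 with an estimated correlation.

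Some cell cycle genes rose as well. Of 37 mitosis genes, 12 rose and none fell, and 35 rose adjusted over the list alone. The survivin gene Birc5 rose by 2.42 on the log2 scale, the mitotic kinase Cdk1 by 2.12 and the ubiquitin-conjugating enzyme gene Ube2c by 1.94, while the checkpoint gene Mad2l1 was at 1.95 with an adjusted p of 0.104. Birc5 and Cdk1 lost their calls without any 1 of the fresh arrays, and Cdk1 also without cultured replicate 3. Of 43 genes of DNA replication and S phase, 5 rose and none fell, and 15 rose adjusted over the list alone. Rrm2 was followed by the cyclin Ccna2, which rose by 1.93, while Rrm1 (1.82, and 1.17 without cultured replicate 1) and the thymidine kinase Tk1 (1.30, and 0.46 by a further probe set) had adjusted p of 0.110 and 0.0799. The mitosis list had a camera adjusted p of 4.00e-21 and an adjusted p of 0.135 with an estimated correlation, and the S phase list 6.92e-12 and an adjusted p of 0.256 with an estimated correlation, so that both calls were lost. The p53 target list split. Of 20 members, 3 rose, namely Ccng1, Zmat3 (1.40) and Phlda3 (1.12), and 4 fell, namely Btg2, Fas (-2.98), Gadd45a (-2.13) and Plk2 (-1.94), and 6 rose and 6 fell adjusted over the list alone. It was not past the set test, with an adjusted p of 0.315.

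Cytoskeleton and focal adhesion genes had 6 of 30 members higher and none lower, and 8 higher and 5 lower adjusted over the list alone. S100a4 was followed by the tropomyosin Tpm1 (2.49) and the myosin light chain Myl9 (1.84), while the smooth-muscle protein gene Tagln was at -1.84 with an adjusted p of 0.0622. Tpm1 lost its call without fresh replicate 2, fresh replicate 3 or cultured replicate 3, at adjusted p of up to 0.0748. The list had a camera adjusted p of 0.0202, lost at an adjusted p of 0.735 with an estimated correlation, at 0.0570 without fresh replicate 1 and at 0.549 without cultured replicate 1. Over 22 other settings the call was kept in 16 and lost in 6. After quantile normalization the camera adjusted p was 3.12e-09, and with cyclic loess 1.18e-08, at medians of 0.75 and 0.65. On the deposited scale the median of 0.33 lay above the -0.70 to -0.0008 that held 95% of random lists matched on brightness. Extracellular matrix genes had 6 of 34 members lower and none higher, and 11 lower and 4 higher adjusted over the list alone. The proteoglycan Bgn fell by 1.85 on the log2 scale and the gelatinase Mmp2 by 1.68, while the protease inhibitor Timp1 (1.90) and the matrix protein Tnc (1.38) had adjusted p of 0.0767 and 0.0507. The camera adjusted p was 0.0170, lost at an adjusted p of 0.510 with an estimated correlation, at 0.177 without cultured replicate 2 and at 0.117 after quantile normalization. For extracellular matrix the call was kept in 12 of the 22 other settings and lost in 10. Its median of -0.12 lay within the -0.14 to 0.17 that held 95% of matched random lists. Of the fibroblast markers, Dpt, Dcn, Apod and Gsn fell beside it.

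Interferon response genes had 4 of 25 members lower and none higher, and 6 lower adjusted over the list alone. They were the transcription factor Irf1 (-3.33, and -1.37 by a further probe set), the major histocompatibility light chain B2m (-3.31), Ifi27 (-1.55) and the exonuclease Isg20 (-1.30). Ifi27 lost its call without fresh replicate 1, fresh replicate 3 or cultured replicate 3, at adjusted p of up to 0.0995. The list had a camera adjusted p of 0.000492, lost at an adjusted p of 0.0770 with an estimated correlation. Of 17 circadian clock genes 8 fell and none rose, and 9 fell adjusted over the list alone, among them the repressors Nfil3 (-3.82) and Nr1d1 (-3.33), Rora (-2.12) and Bhlhe40 (-1.89). This list had a camera adjusted p of 3.18e-10, lost at an adjusted p of 0.102 with an estimated correlation.

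Cytosolic ribosomal protein genes had 6 of 21 members lower and none higher, and 20 lower adjusted over the list alone. Their array medians were 11.37, 11.39 and 11.34 on the fresh arrays, and 10.79, 8.67 and 9.23 on cultured replicates 1, 2 and 3. Rpl13 fell by 2.28 on the log2 scale, while Rpl7 (-2.53), Rpl28 (-2.43) and Rpl23 (-2.30) had adjusted p of 0.155, 0.193 and 0.197. Rpl28 and Rpl23, at 14.35 and 14.68 on the fresh arrays, were near the top of the array range, so their differences can be understated. Without cultured replicate 1, Rpl7, Rpl28 and Rpl23 passed at -3.62, -3.60 and -3.42 with adjusted p of 7.63e-05, 3.45e-05 and 2.67e-05, and without cultured replicate 2 they did not, at -1.74, -1.65 and -1.58. Rpl13 lost its call without any 1 of the fresh arrays or without cultured replicate 3. The list had a camera adjusted p of 4.03e-14, lost at an adjusted p of 0.267 with an estimated correlation. The median fold change of the ribosomal protein list was -1.99, but -0.68 after quantile normalization and -0.33 with cyclic loess. It still passed camera there, at adjusted p of 3.12e-09 and 1.78e-06. Of 34 ribosome biogenesis genes 1 fell, Rrp9 at -0.88, singled out after its value was seen, and none rose, and 3 fell adjusted over the list alone. The list median was -0.19, but 0.10 after quantile normalization, and -0.53 without cultured replicate 1 at an adjusted p of 9.73e-07. It lay within the -0.42 to 0.09 that held 95% of matched random lists. Nop58 was at -2.09 with an adjusted p of 0.0597 and Gnl3 at -1.97 with 0.0762, and both passed without cultured replicate 1, at -2.72 and -2.63 with adjusted p of 6.04e-05 and 5.33e-05. The camera adjusted p of 0.0375 was lost at an adjusted p of 0.735 with an estimated correlation and without fresh replicate 2, cultured replicate 2 or cultured replicate 3, at 0.230, 0.339 and 0.135. For ribosome biogenesis the call was kept in 8 of 22 other settings and lost in 13, and the direction was reversed in 1.

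Metabolic gene lists did not pass the set test. Nuclear genes of oxidative phosphorylation had 1 of 44 members higher, Cyc1 at 0.92, and none lower, and 1 higher adjusted over the list alone, with a median of 0.04 and a camera adjusted p of 0.702. That median lay above that of random lists matched on brightness, whose median was -0.57, with 95% of them from -0.96 to -0.23. Cox4i1 was at -1.14 and Ndufa4 at 1.05, with adjusted p of 0.0593 and 0.168. This list depended on single arrays, with a median of -0.23 and an adjusted p of 0.00228 without cultured replicate 1, and 0.30 and 0.00155 without cultured replicate 2. It passed upward after quantile normalization, at a median of 0.64 and an adjusted p of 3.66e-13, as did glycolysis at 0.33 and 0.0177. In glycolysis, with a camera adjusted p of 0.475, the muscle enolase Eno3 rose by 2.27 and the platelet phosphofructokinase Pfkp fell by 2.11, the only 2 of 19 members past the test, and 4 were higher and 3 lower adjusted over the list alone. The probe sets of Hk1 disagreed, at -2.35 and -0.30, and neither passed; the first passed without cultured replicate 1, at -3.38 and an adjusted p of 9.43e-05, and was at -1.63 with 0.269 without cultured replicate 2. Cholesterol synthesis had none of 18 members past limma's test over all genes or adjusted over the list alone. At an unadjusted p of 0.05 it had 1, and the camera adjusted p was 0.315. An unmoderated test with unequal variances passed 0 of them. That test passed only 14 of all genes, and none of the heat shock or mitosis lists, so this 0 says little. Nsdhl was at 0.75 and Msmo1 at -0.54. Of 25 genes of NAD metabolism and ADP-ribosylation, the deacetylase Sirt2 (-1.35) and Parp3 (-0.90) fell, and the same number fell adjusted over the list alone, with a camera adjusted p of 0.690. Parp3 lost its call without fresh replicate 2, fresh replicate 3, cultured replicate 2 or cultured replicate 3, at adjusted p of up to 0.125. None of the 15 mitochondrially encoded transcripts was named by a probe set here.

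**Figure D3:**
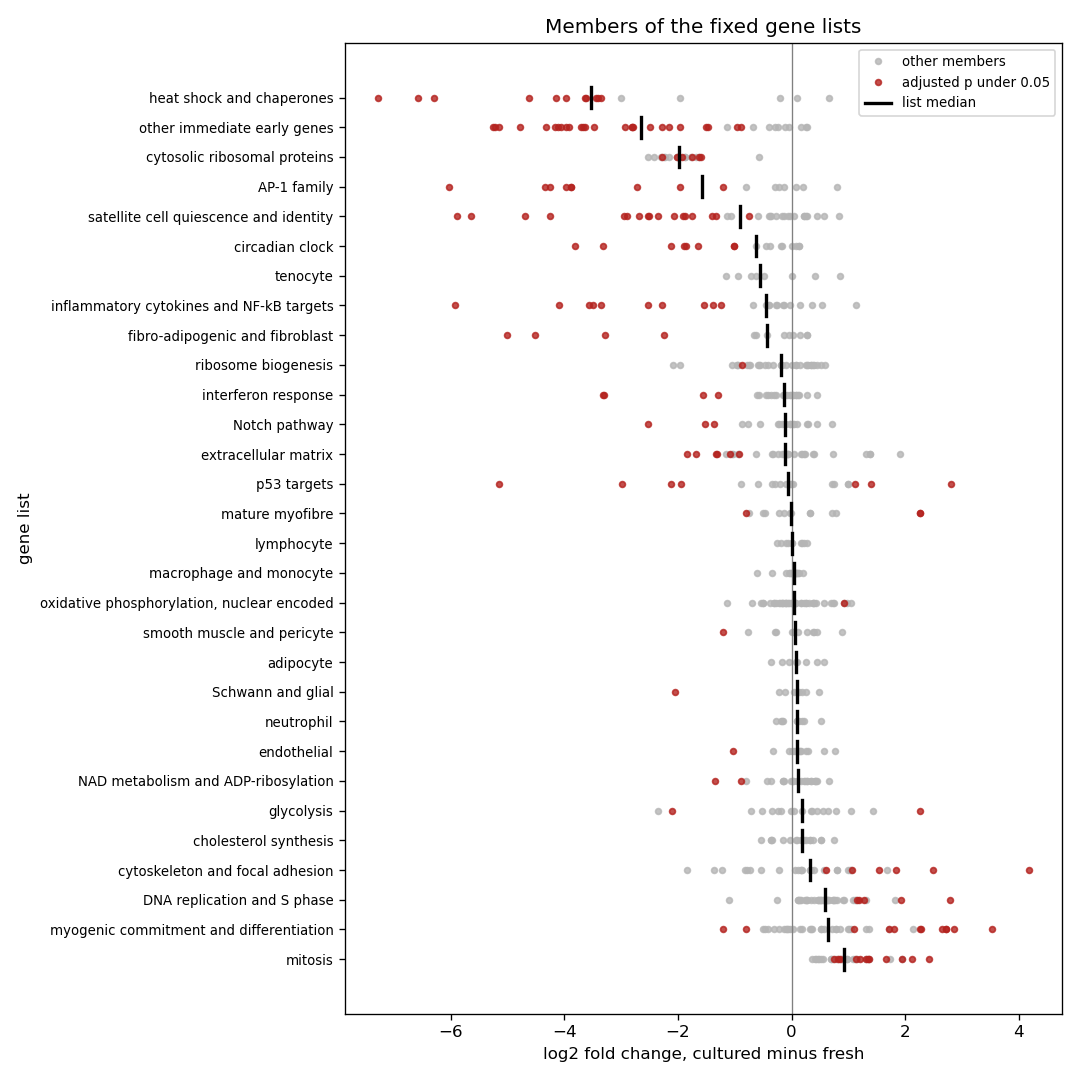
Log2 fold change, cultured minus fresh (horizontal axis), of each member of the fixed gene lists with at least 5 measured genes (vertical axis), with members past an adjusted p of 0.05 in red, others in grey and a black bar at the list median. Medians run from -3.53 for heat shock proteins and chaperones to 0.92 for mitosis genes.

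Markers of other cell types differed in level between lists, and 12 of 15 macrophage but 1 of 14 mature myofibre markers lay within background in both groups. Of 13 fibro-adipogenic and fibroblast markers 4 fell and none rose, and 5 fell adjusted over the list alone. Dpt, a matrix protein, fell by 5.02 on the log2 scale and the proteoglycan Dcn by 4.52, both to within background. The lipid carrier Apod fell by 3.29 and the actin-severing Gsn fell by 2.25. Dcn differed between the fresh arrays, at 8.53, 7.78 and 5.86. The list had a camera adjusted p of 0.000174, lost at an adjusted p of 0.105 with an estimated correlation. It fell beside the matrix and quiescence genes above. Whether these markers fell within satellite cells or came from other cells in the fresh sort was not tested. The sort marker Cxcr4 fell by 2.47 and Itgb1 was at -0.55 with an adjusted p of 0.602, while Ptprc, Pecam1 and Itgam, which the gate excludes, lay within the receptor gene background in both groups. Only these 3 of the 5 excluded markers were measured. The genes of Ter119 and Sca1 were not, so the values do not show how well the gate removed cells carrying them.

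Endothelial genes had 1 of 15 members lower, Rgcc at -1.03, and 1 lower and 1 higher adjusted over the list alone. Smooth muscle and pericyte genes had 1 of 12 lower, Des, and 2 lower adjusted over the list alone, and Schwann and glial genes had 1 of 9 lower, Pmp22 at -2.05, with the same count adjusted over the list alone. Mature myofibre genes had 2 of 14 higher, Eno3 and Mylpf, and Ckm lower, with 2 higher and 2 lower adjusted over the list alone. Macrophage, neutrophil, lymphocyte, tenocyte and adipocyte lists had no member past limma's test over all genes. At an unadjusted p of 0.05 they had 1 of 15, 1 of 10, 0 of 10, 2 of 8 and 2 of 8. None passed an unmoderated test with unequal variances, which says little, since that test passed only 14 of all genes. Adjusted over the list alone, 1 tenocyte gene, Scx at 0.86, and 1 adipocyte gene, Plin1 at 0.57, were higher. Rgcc lost its call without fresh replicate 1, fresh replicate 3 or cultured replicate 3, at adjusted p of up to 0.0730. Pmp22 lost it without fresh replicate 2 or fresh replicate 3, at up to 0.0695. None of these lists passed the set test, with camera adjusted p of 0.969 for each. Median, mean and test differed in sign for lymphocytes (0.01, 0.03, down), macrophages (0.04, -0.02, down), Schwann cells (0.09, -0.13, up) and myofibres (-0.02, 0.27, up), and the smooth muscle median was 0.06 with the test down. Only 3 of 11 erythroid genes were measured, Alas2, Epb42 and Slc4a1, at -0.21, -0.03 and 0.03. Some tenocyte list members were higher on fresh replicate 1, with the cartilage and tendon matrix gene Chad at 6.78 against 3.56 and 3.97 on the other fresh arrays and Fmod at 6.08 against 3.35 and 2.57, while the tendon transcription factor Scx was at 5.26 against 5.23 and 4.69.

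The cultured arrays did not share one brightness range. Among 49 genes with a mean over the 6 arrays above 11, the median difference from the fresh mean was -0.09 on cultured replicate 1, -3.33 on replicate 2 and -2.87 on replicate 3. Without cultured replicates 2 and 3 together, a comparison added after seeing the data in which the lone cultured array is assumed to vary like the fresh arrays, 838 genes passed the test, 474 of them higher and 364 lower in culture. Fos was at -6.32 in that comparison. The oxidative phosphorylation, glycolysis and cholesterol synthesis lists passed the set test upward there, at medians of 0.77, 0.34 and 0.61, and extracellular matrix no longer passed, at an adjusted p of 0.237.

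**Figure D4:**
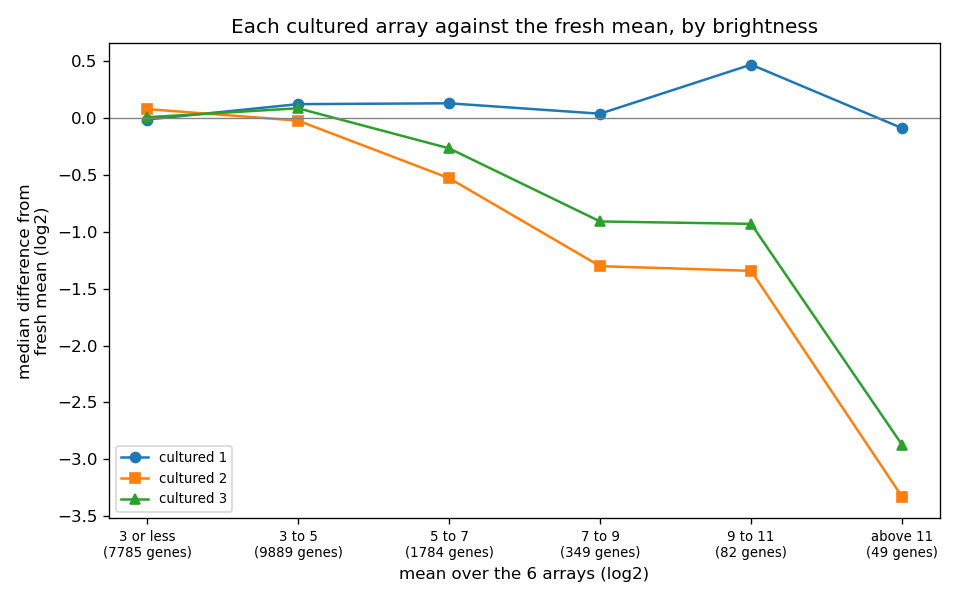
Median difference of each cultured array from the mean of the fresh arrays (vertical axis, log2) over genes grouped by their mean over the 6 arrays (horizontal axis, log2, with the number of genes), 1 line per cultured array. Replicates 2 and 3 fall to -3.33 and -2.87 in the brightest group, where replicate 1 is at -0.09.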

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

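Probe sets that name no single gene were outside the comparison of genes. Of 13767 such probe sets tested with limma in the same way, 208 passed an adjusted p of 0.05, 22 higher and 186 lower in cultured than in fresh cells. The 22 are a signal above the level of the fresh cells in data the comparison of genes does not use, and no explanation was tested for them.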

How the results depend on the processing

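Leaving out cultured replicates 2 and 3 together was chosen after the data were seen, and the other settings before. Of 77 named genes past the test, 58 kept it without any 1 array and 19 lost it. None changed sign, which could not have come out otherwise, since the groups of every gene past the test do not overlap. Leaving out each array gave 448 to 1517 changed genes, 433 to 1156 at least 2-fold, and a share higher of 10.8% to 34.7%. Arrays with a weaker bright range and few arrays limit precision, and the cause of each change below was not tested unless given.

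The number of changed genes rose to 1742 with array weights, 1511 with quantile normalization (829 of the 861 shared in direction, 0 opposite) and 1492 with cyclic loess, and fell to 14 with an unmoderated test with unequal variances (13 at least 2-fold, 7.14% higher, 1 AP-1 member). Under ribosomal protein centring 18283 changed, all at least 2-fold. The share of higher genes was 26.0% with a trended and robust prior, 33.6% with array weights, 38.8% with quantile normalization, 18.1% with median centring, 99.4% with ribosomal protein centring, 30.6% with cyclic loess, 18.3% with every probe set and 56.6% without cultured replicates 2 and 3. A replicate block gave 662 genes, 15.3% of them higher. Same-numbered arrays did not deviate together (correlations of -0.0898, -0.144 and 0.0345), and not every array correlated best with its own number. The cultured deviations also hold the difference in bright range, which can hide a shared mouse, so these correlations do not decide on pairing. With an estimated correlation 3 pathway lists and 0 other-cell-type lists passed camera, and 0 of the latter passed on ranks.

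Ribosomal protein centring added 1.81 to every log2 fold change, which leaves changes relative to all genes as they are and by construction turned Fosl2 (0.61), Batf (1.58), Batf3 (1.67), Mafg (1.51), Hes1 (0.29), Hey1 (0.45), Msmo1 (1.27), Sirt2 (0.45), Parp3 (0.91), Mmp2 (0.13), Ifi27 (0.26), Isg20 (0.51), Rgcc (0.78), Cd36 (1.47), Des (0.60), Cd14 (1.46), Csf3r (1.54), Ly6g (1.62), Cd3g (1.54), Cd3d (1.62), Alas2 (1.59), Epb42 (1.78), Sox10 (1.59), Ckm (1.01), Lpl (1.45), Pax7 (0.48) and Myod1 (1.39) positive. Relative to all genes, 15 of 16 list tests past the threshold kept their sign in every rescaling, the exception being ribosome biogenesis. Median centring and ribosomal protein centring shift all genes of an array alike, so they could not change these signs. Only quantile normalization and cyclic loess put them to the test. The oxidative phosphorylation list turned to -0.23 without cultured replicate 1 and was at 0.30 without cultured replicate 2, and ribosome biogenesis to 0.20 without cultured replicates 2 and 3.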

Other observations

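Of 51 measured small nucleolar RNA genes, which guide the modification of ribosomal RNA, 37 fell and none rose in cultured cells, with a median of -2.30. Bright members were lower on cultured replicates 2 and 3 than on replicate 1, with Snord15a at 7.93 and 8.54 against 10.36 and Snord15b at 8.98 and 10.20 against 11.83. Of 28 genes of the histone clusters, 7 rose, among them H2ac4, and 1 fell, with a median of 0.32. Both groups were chosen after their values were seen and have no set test. The histone H2bc4 was the one that fell, at -1.68.

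In the paragraphs on ribosomal proteins and on stress genes, the test on bright genes and the count of heat shock genes were chosen after the results were seen, and the other tests before.

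The first pattern is the lower level of cytosolic ribosomal proteins in culture. A loss of bright signal on cultured replicates 2 and 3 is a candidate explanation: over 87 genes outside the ribosomal proteins with a mean above 9, the median of replicates 2 and 3 minus replicate 1 was -1.83, and all 87 were lower. Whether ribosomal proteins fell beyond that trend stays open. Their median of -1.99 lay at a percentile of 0.07 among random lists matched on brightness, past the bound set beforehand, but a check added after that result found the matched genes dimmer, at a median of 9.91 against 10.37, so the test decides nothing. The median of the list was -0.68 after quantile normalization and -0.33 with cyclic loess, so the size of the fall depends on the scaling. On cultured replicate 1 the list was -0.35 from the fresh mean, and a true difference between the culture dishes was not tested.

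The second pattern is the high level of AP-1, other immediate early and heat shock genes in fresh cells. The loss of bright signal is argued against as the whole cause, since the median of the 68 genes, -2.81, lay at a percentile of 0.01 among matched random lists, the smallest they can give, and was -2.17 on cultured replicate 1. Tissue dissociation and sorting just before lysis may also raise these genes. The 11 heat shock genes lower in culture are what it needs, but every fresh array came from sorted cells, so it cannot be told apart from the state of the cells in muscle. That state, as a biological explanation, stays open and untested.

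The third pattern is the higher level of Mcpt8 and Milr1, genes of basophils and mast cells, in culture. Mast cells or basophils in the culture are argued against as the source, since 16 markers written down before the test had a median log2 fold change of 0.0258, none higher at an adjusted p of 0.05, and 13 within background on cultured arrays. The brightest on cultured arrays were Gata2 at 4.26, Prss34 at 3.44 and Tpsb2 at 3.33, against a background of 3.30, and none of the 16 is held by another list. Gata2 was at 0.69 with an adjusted p of 0.0504, so that 1 marker, just outside the threshold, goes the other way. The gate against CD45 would remove such cells before culture, while cross-hybridisation of the probes and a change in the satellite cells themselves stay open and were not tested.

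Thbs4, named after its values were seen, was at 6.11 on fresh replicate 1 and at 3.89 and 2.98 on the other fresh arrays, beside Chad, Fmod and Tnmd, the last at 4.86 against 2.57 and 2.93.

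Splitting the 6 arrays into 3 and 3 can be done in 10 ways, the real one included, so a share under 0.05 cannot be reached. The real split gave 861 genes, 689 of them at least 2-fold, with 9 AP-1 members lower, 1 split of 10 in each case, while the highest other split gave 0. It gave 15 pathway lists, 1 split of 10, against 13 in the highest other split, and 1 other-cell-type list, reached by 4 of 10, against 3. The set test at the preset correlation thus calls many lists in splits that mix the groups. Each mixed split is unbalanced, so part of the real difference stays in its contrast and part adds to the spread. Neither the lists called there nor the 0 genes therefore show what arrays without a difference would give.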
